A study of Mus musculus with 8 samples.

How the data were processed

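Messenger RNA was purified with poly-T beads from the total RNA of cultured forelimb buds, fragmented and turned into complementary DNA with random primers, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, STAR 2.5, HTSeq 0.6.1 and DESeq2 (version given as 2), and the genome build mm10; the roles of these tools, the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table with 21692 genes. Per the file headers it holds, for each of 8 libraries, raw read counts per gene, counts divided by a size factor, and FPKM values, together with the authors' log2 fold change and p-value columns (unadjusted and adjusted). The column of deposited signal values is the count divided by 1 constant per library, between 0.80311 and 1.2451, and the deposited FPKM values divide the counts by the gene length column and by the total of the counts; these were checked on the values and neither was used for a test. The authors' deposited adjusted p-value is missing (NA) for 3933 genes, which were kept as missing.

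Libraries were assigned to the vehicle and OPE groups by their titles in the labels, and all 8 were used, 4 in each group. No row without a gene name was present. Totals of reads counted to genes ranged from 14986793 to 22006738. No pair of libraries of a group agreed within counting noise (chi-square per degree of freedom at least 5.03), so none was counted as a repeat of another; the correlation of log2 CPM within groups lay between 0.963 and 0.992.

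The raw counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit at the package defaults, two-sided), with group as the only term and Benjamini-Hochberg adjustment at 0.05. Of the 21692 genes, 15517 passed the filter. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common dispersion was 0.0259, a biological coefficient of variation of 0.161. CPM values use TMM-scaled totals, and log2 CPM values for plots and list medians have a prior count of 2. Gene lists were tested with camera in limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, adjusted over 36 lists, with camera at an estimated correlation and fry beside it. Of the 16 lists that passed, none passed with an estimated correlation and 6 passed fry, whose p-value asks whether the genes of a list move, on balance, one way. Library properties were compared with an exact permutation test over the 70 assignments of 8 libraries to 4 and 4. Ratios of low read counts carry exact 95% binomial intervals, which cover counting error only, since reads amplified by PCR are not independent molecules.

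The 36 lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule took the 10 genes of largest fold change in each direction among those past the threshold with a mean of at least 1 CPM and no overlap between groups, the 5 of smallest p in each direction, up to 4 members of smallest p in each list, and 12 markers of ossification and hedgehog signalling whatever their p; predicted genes without a symbol were counted and not named. It gave 158 tested genes, of which 36 passed; 1 result for a single gene is not reported here. Where fewer passed, all that passed were taken. Of the 10 library properties, the detected genes at equal depth and the slopes on gene length and on GC content were added after the data had been seen. In addition, 7 lists (lysosome, aminoacyl-tRNA synthetases, LXR targets, intestinal epithelium, osteoclast, apical ectodermal ridge and yolk sac endoderm) were written after the data had been seen.

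The same steps were tested on simulated data with the real means, totals and dispersions, 4 against 4 libraries and 15344 genes tested. Of genes changed 1.5-fold, 29.9% were called, of those changed 2-fold 78.1%, and of those changed 4-fold 95.4%. Of the 138 calls 6 were unchanged genes. No gene was called when nothing was changed, and none of 20 lists of unchanged genes was called. The simulated genes varied independently of one another, without a gene-length trend or an outlying library. The simulation therefore does not show how often camera passes unchanged lists whose genes vary together.

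Alternatives covered other scaling (the size factors of DESeq2, library totals, upper quartile), other filters, DESeq2 1.42.0, limma-voom with and without sample weights, a fit that is not robust, stricter thresholds, the replicate number as a block, and leaving out each library. Chosen after seeing the data were offsets that remove a spline trend of gene length, or of gene length and transcript GC content, from each library, a fit without both OPE 1 and OPE 3, and the newer quasi-likelihood method of edgeR. The design named the edgeR test without choosing between its default and its newer method. The default was kept as the design's reading when the counts from both, 74 and 112 genes, had already been seen. Transcript GC content came from GENCODE M21, which matched 21457 of the 21692 gene identifiers and gave the same chromosome and strand and an overlapping position for 21445. Coordinates are those of the deposited table (mm10). Of the 74 genes called, 12 overlap another gene of the table, 10 of them only on the opposite strand. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.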

Results

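RNA from cultured mouse forelimb buds was sequenced in 8 libraries. The buds came from CD1 embryos of gestation day 13 and were kept in culture for 24 h, either with the vehicle dimethyl sulfoxide or with a mixture of organophosphate esters (OPE), flame retardants and plasticisers that escape from products into house dust. The mixture was modelled on house dust and was added at a dilution of 1 in 300000. Each group had 4 libraries, here called vehicle 1 to 4 and OPE 1 to 4. The deposited counts summed to between 17549560 and 22006738 reads per vehicle library and between 14986793 and 21806141 per OPE library. OPE 3 stood apart on the first principal component of log2 CPM and OPE 1 on the second. The labels do not say whether the replicates of a group came from separate litters or cultures, so the p-values measure the spread between these samples, part of which can be technical.

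The comparison asked how the mixture changes gene expression while limb cartilage is on its way to bone by endochondral ossification. Macrophage genes, genes of late cartilage and of bone-forming cells, and several endothelial and lipid-handling genes fell with OPE. Csf1r, the receptor that macrophages need to survive, fell by 2.51 ± 0.24 (SE) on the log2 scale, from 22.3 ± 2.75 to 3.97 ± 1.53 CPM (counts scaled to library size; mean ± SD, n = 4 libraries per group; edgeR adjusted p = 0.00369). Lpl, which encodes lipoprotein lipase, fell by 1.07 ± 0.09 (adjusted p = 0.00235). Bmp7, which encodes a bone morphogenetic protein, fell by 0.75 ± 0.08 (adjusted p = 0.00539). In the other direction, the stress-induced cytokine gene Gdf15 rose by 2.95 ± 0.34 (adjusted p = 0.0071). The cholesterol synthesis genes Msmo1 and Cyp51 rose by 0.95 ± 0.17 and 0.63 ± 0.11 (adjusted p = 0.0388 for each). The early cartilage genes Sox9, Col2a1 and Acan gave log2 fold changes of -0.02 ± 0.12, -0.06 ± 0.12 and -0.09 ± 0.11, with adjusted p of 0.974, 0.892 and 0.80. In the mm10 genome Lpl lies on chromosome 8 (68880491 to 68907448), Gdf15 on chromosome 8 (70629393 to 70632456) and Bmp7 on chromosome 2 (172868012 to 172940321).

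Of 15517 genes tested, 74 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 68 of them lower and 6 higher with OPE, and 45 of them changed at least 2-fold. In all 74 the 4 OPE values lay outside the range of the 4 vehicle values, as they did in 9.49% of the genes tested, against 2.86% expected by chance. The count depended on which libraries entered. It was 8, 7, 19 and 7 without vehicle 1, 2, 3 or 4. It was 58, 12, 308 and 178 without OPE 1, 2, 3 or 4, and 37 of the 58 were among the 74. Without both OPE 1 and OPE 3 the count was 85, of which 48 were among the 74. The preponderance of lower genes depended on the treatment of gene length: removing each library's gene-length trend gave 321 genes, 170 lower and 151 higher, and removing trends of length and GC content gave 357, 176 lower and 181 higher. The genes Lpl, Csf1r, Aplnr, Stab1, Abcg1, Bmp7 and Gdf15 passed in all 8 fits that left out 1 library, and the other 29 of the 36 named genes that passed lost the call in at least 1 of these fits. Of 36 gene lists 16 passed camera at its preset correlation, 11 lower and 5 higher, and none passed with an estimated correlation. With fry 6 of the 16 passed. They were the macrophage and leukocyte, hypertrophic chondrocyte, osteoblast, G2 and M phase, cholesterol synthesis, and fatty acid and adipocyte lists. The rest of the 16, said below to rise or fall as groups, did so by camera at the preset correlation only. As many lists passed in 6 of the 35 ways to split the 8 libraries into 4 and 4, the real one included.

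**Figure D1:**
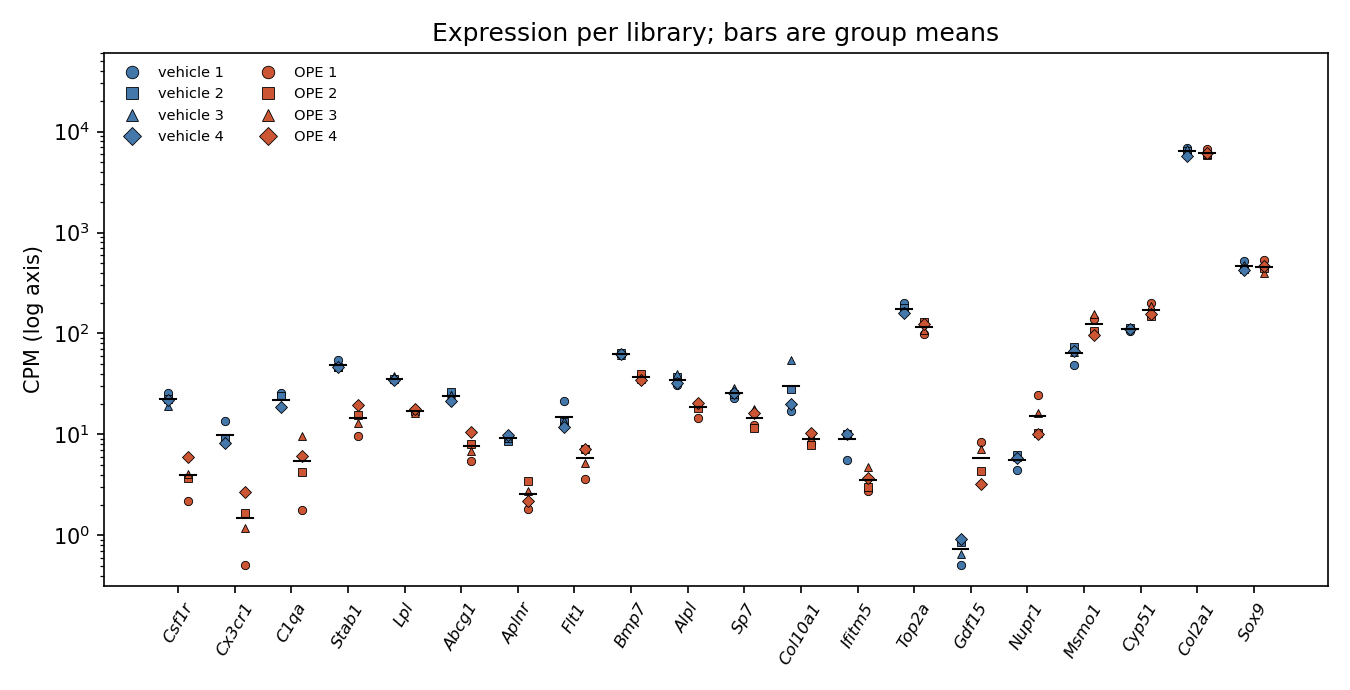
CPM of 20 named genes in each library (log axis). Blue symbols are the 4 vehicle libraries, red symbols the 4 OPE libraries, symbol shapes give the replicate number and bars are group means; Csf1r averaged 22.3 CPM with vehicle and 3.97 CPM with OPE, Gdf15 averaged 0.741 and 5.78 CPM, and Col2a1 averaged 6424 and 6160 CPM.

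Macrophage genes formed the group with the largest fall. All 21 members of the macrophage and leukocyte list had a log2 fold change below 0, with a median of -1.19, and 8 fell past the threshold over all genes (18 adjusted over the list alone; the other 13 did not pass over all genes). They included Cx3cr1, a chemokine receptor of tissue macrophages (-2.76 ± 0.37, adjusted p = 0.0158), Spi1, the myeloid transcription factor PU.1 (-1.23 ± 0.18, adjusted p = 0.0209), and the complement genes C1qa and C1qc (-2.04 ± 0.36 and -2.01 ± 0.38). The list fell as a group (camera adjusted p = 7.37e-25), and its adjusted p was 0.17 with an estimated correlation. Its median relative to the vehicle mean lay between -0.90 and -2.22 in the 4 OPE libraries and between -0.16 and 0.13 in the vehicle libraries, and OPE 1 was the lowest. Outside the list, C3ar1, the receptor of the complement fragment C3a, fell by 2.35 ± 0.31, and Stab1, a scavenger receptor of macrophages and some endothelia, fell by 1.75 ± 0.18. Csf1r lies on chromosome 18 (61105572 to 61132149, mm10) and overlaps Hmgxb3 on the other strand. Of the 74 genes 12 overlap another counted gene, among them Stab1, Cx3cr1 and Col10a1, where the other gene holds many reads, and Col22a1 and Runx3, where it holds 0.456% and 0.6% of the gene's own count. The values of Csf1r, Stab1 and Col10a1 are uncertain to that extent, since whether the counting used strand is not given in the sources used here. Cx3cr1 also overlaps Gorasp1, Csrnp1 and Xirp1 on its own strand, so its value would stay uncertain with stranded counting.

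Endothelial genes were lower, mostly in OPE 1. Of 21 members, 2 fell over all genes, namely Aplnr, the apelin receptor (-1.87 ± 0.20, adjusted p = 0.00441), and Flt1, a receptor of vascular endothelial growth factors (-1.37 ± 0.25, adjusted p = 0.0452); 7 fell adjusted over the list alone and 19 did not pass. The pan-endothelial genes Cdh5 and Pecam1 gave -0.84 ± 0.21 and -0.70 ± 0.18 (adjusted p = 0.103 and 0.117). The list fell as a group (camera adjusted p = 6.15e-09; adjusted p = 0.33 with an estimated correlation), with a median of -1.01 in OPE 1 against -0.34, -0.15 and -0.28 in OPE 2, 3 and 4; the value of OPE 3 lay inside the vehicle range. Among the blood genes, none of the 11 erythroid genes tested passed, and the erythroid list did not move as a group (camera adjusted p = 0.881, median 0.14); haemoglobin took 0.153 ± 0.0616% of the counts with OPE and 0.128 ± 0.0218% with vehicle.

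Genes of the late stages of endochondral ossification fell. Of 17 hypertrophic chondrocyte genes, 4 fell over all genes and 10 adjusted over the list alone: Alpl, alkaline phosphatase (-0.91 ± 0.14, adjusted p = 0.0248), Runx3 (-0.78 ± 0.14, adjusted p = 0.0388), Sp7, the transcription factor osterix (-0.83 ± 0.15, adjusted p = 0.0452), and Col10a1, the collagen X chain that marks hypertrophic cartilage (-1.73 ± 0.33, adjusted p = 0.0493). Col10a1 averaged 9.1 ± 1.2 CPM with OPE and 30.2 ± 17.4 CPM with vehicle, and it passed in 4 of 14 settings, with adjusted p from 1.2e-05 to 0.472. The osteoblast list is not separate from the hypertrophic list: before the expression filter, 7 of its 23 members were also in that list. Of 20 osteoblast genes tested, 4 fell over all genes and 11 adjusted over the list alone, among them Ifitm5, a gene of mineralising osteoblasts (-1.36 ± 0.24, adjusted p = 0.0417), and Col13a1 (-0.75 ± 0.13, adjusted p = 0.0388). Runx2, the master regulator of osteoblasts, gave -0.65 ± 0.14 (adjusted p = 0.0776). Both lists fell as groups (camera adjusted p = 2.26e-08 and 1.38e-11; adjusted p = 0.16 for each with an estimated correlation), and their medians were below those of all 4 vehicle libraries in all 4 OPE libraries. The list of cartilage matrix and chondrocyte genes had no member past the threshold among 32, over all genes or over the list alone, and a median of -0.08 (camera adjusted p = 0.0999).

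Hedgehog signalling controls the pace of cartilage maturation. The ligand gene Ihh gave 0.32 ± 0.15 (adjusted p = 0.417), and the targets Gli1, Ptch1 and Hhip gave -0.29 ± 0.12, -0.76 ± 0.37 and -0.57 ± 0.16 (adjusted p = 0.321, 0.414 and 0.158); the hedgehog list did not move as a group (camera adjusted p = 0.421). Shh and Mmp13 were too low to be tested. Shh had 9 reads over the OPE libraries and 10 over the vehicle libraries, so no difference was detectable at this depth (ratio of depth-scaled reads 1.1, exact 95% interval 0.397 to 3.02). Mmp13, a collagenase of terminal hypertrophic cartilage, had 159 reads with OPE and 29 with vehicle (ratio 6.73, exact 95% interval 4.51 to 10.4, counting error only), and 111 of the 159 came from OPE 1.

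Cell cycle genes were lower with OPE by a modest amount. Of 54 genes of G2 and M phase, 51 had a log2 fold change below 0 and 2 fell over all genes, Hmmr (-0.65 ± 0.12, adjusted p = 0.0389) and Top2a, topoisomerase II alpha (-0.62 ± 0.11, adjusted p = 0.0451); 31 fell adjusted over the list alone. Of 41 S phase genes, none passed over all genes and 20 fell adjusted over the list alone, for example Rrm2, a ribonucleotide reductase subunit (-0.68 ± 0.17, adjusted p = 0.104 over all genes). Both lists fell as groups (camera adjusted p = 8.03e-24 and 1.56e-16; adjusted p = 0.16 and 0.33 with an estimated correlation). The S phase median was -0.72 in OPE 1 and between -0.32 and -0.19 in the other OPE libraries.

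Stress response and sterol genes were higher. Of 39 genes of the integrated stress and unfolded protein responses, 1 rose over all genes, Nupr1, a stress-induced chromatin protein (1.45 ± 0.27, adjusted p = 0.0484), while 24 rose and 2 fell adjusted over the list alone. Asns and Mthfd2, targets of the transcription factor ATF4 in amino acid and folate metabolism, gave 1.05 ± 0.20 and 1.00 ± 0.20 (adjusted p = 0.0504 and 0.0522). The list rose as a group (camera adjusted p = 2.01e-09; adjusted p = 0.33 with an estimated correlation), with medians of 1.08 in OPE 1 and 0.42, 0.22 and 0.14 in OPE 3, 2 and 4, and the highest vehicle median was also 0.14. Among 32 p53 targets Gdf15 alone passed, which the integrated stress response also induces; the list rose (camera adjusted p = 0.00956; adjusted p = 0.49 with an estimated correlation) but not without OPE 1 (adjusted p = 0.121). Of 26 cholesterol synthesis genes, 25 had a log2 fold change above 0, 2 rose over all genes (Cyp51, lanosterol demethylase, and Msmo1) and 20 adjusted over the list alone. Hmgcs1, which encodes the synthase of HMG-CoA, and the sterol sensor gene Insig1 gave 0.51 ± 0.10 and 0.72 ± 0.14 (adjusted p = 0.0522 and 0.0535). This list rose as a group (camera adjusted p = 1.66e-17; adjusted p = 0.16 with an estimated correlation), with medians of 0.35 to 0.55 in the OPE libraries and at most 0.11 in the vehicle libraries.

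In the fatty acid and adipocyte list 2 of 33 genes fell, Lpl and the fatty acid transporter gene Cd36 (-1.01 ± 0.19, adjusted p = 0.0484), and 4 fell adjusted over the list alone; the list fell (camera adjusted p = 0.00932; adjusted p = 0.33 with an estimated correlation) but not without OPE 2 (adjusted p = 0.0611). Abcg1, a cholesterol exporter, fell by 1.66 ± 0.18 (adjusted p = 0.0053), and Slc13a5, a citrate transporter, by 2.49 ± 0.42 (adjusted p = 0.0388). Macrophages express Lpl, Cd36 and Abcg1, and the macrophage list was lower in the same libraries.

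Genes of hypoxia and glycolysis were lower on balance but varied within the vehicle group. None of 34 passed over all genes and 29 fell adjusted over the list alone, for example Slc16a3, a lactate exporter (-1.43 ± 0.32, adjusted p = 0.079), and Egln3, an oxygen-sensing hydroxylase (-1.32 ± 0.29, adjusted p = 0.0741). The list fell as a group (camera adjusted p = 1.56e-16; adjusted p = 0.33 with an estimated correlation). Its median was 0.46, 0.25, -0.10 and -0.60 in vehicle 1 to 4 and lay between -0.91 and -0.31 in the OPE libraries, so vehicle 4 was inside the OPE range.

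Patterning, growth factor and connective tissue lists moved little. Fgf4, a growth factor of the apical ectodermal ridge, fell by 1.77 ± 0.27 at low expression (2.22 ± 0.506 to 0.649 ± 0.0731 CPM, adjusted p = 0.0264), and was the only 1 of 45 limb patterning genes to pass; the list as a group rose slightly (median 0.11, camera adjusted p = 0.0398; adjusted p = 0.45 with an estimated correlation), and it did not pass without vehicle 2, vehicle 3 or OPE 2 (adjusted p = 0.0606, 0.171 and 0.225). In the Wnt list 1 of 44 genes passed, the R-spondin receptor gene Lgr6 (-0.78 ± 0.13, adjusted p = 0.036), and the list fell (median -0.09, camera adjusted p = 0.0025; adjusted p = 0.33 with an estimated correlation). The tendon list of 14 genes had none past the threshold over all genes, with 5 lower and 1 higher adjusted over the list alone, and fell (median -0.21, camera adjusted p = 0.00932; adjusted p = 0.33 with an estimated correlation), though not without OPE 2 (adjusted p = 0.103). The epidermis and ectoderm list of 22 genes had none past either threshold and fell as a group (camera adjusted p = 0.00284; adjusted p = 0.56 with an estimated correlation), but not without OPE 4 (adjusted p = 0.516), where its median was -0.90 against 0.41 in OPE 2.

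**Figure D2:**
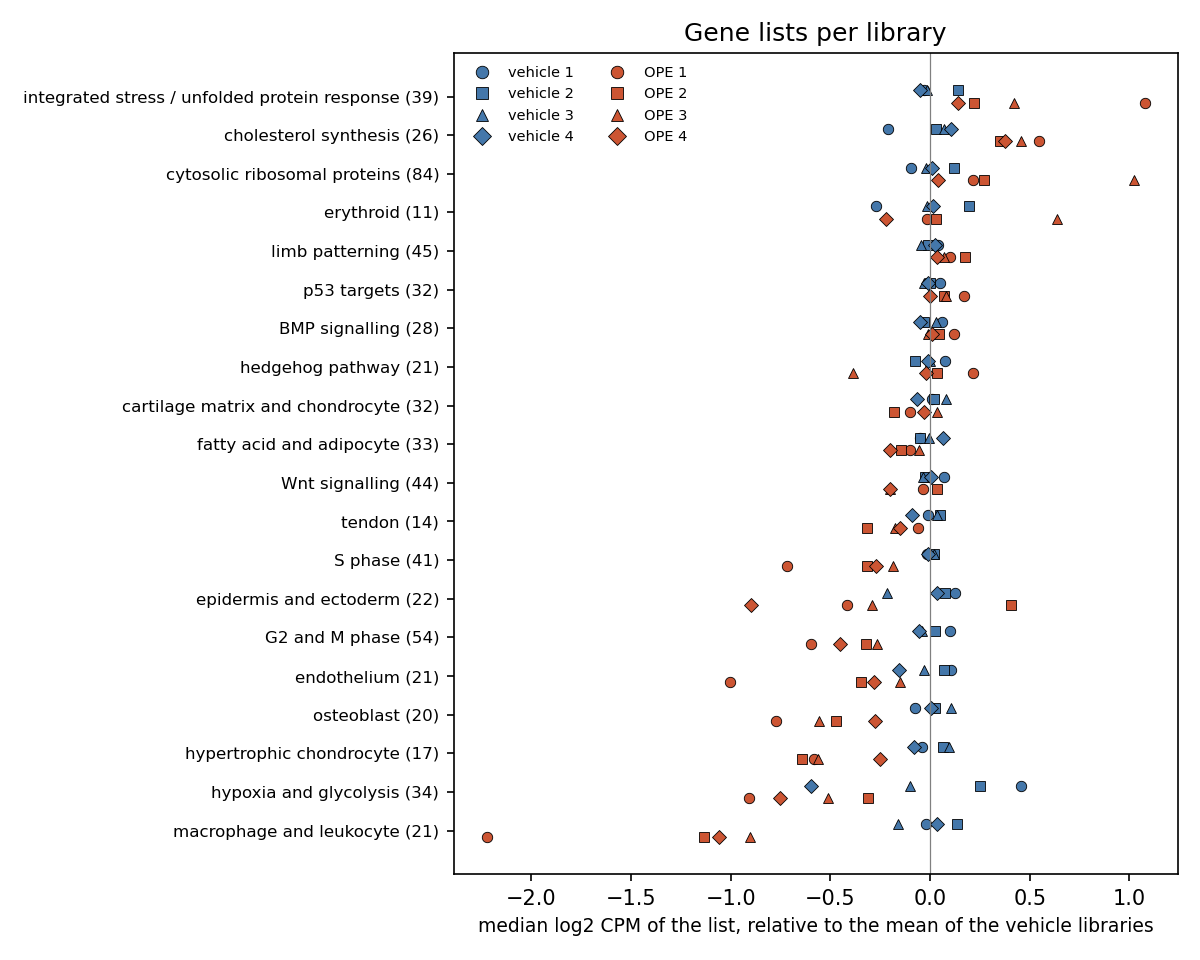
Median log2 CPM of the members of 20 gene lists in each library, relative to the mean of the 4 vehicle libraries, with the number of genes tested in brackets. Blue symbols are vehicle and red symbols OPE libraries; the macrophage list lies between -0.90 and -2.22 in the OPE libraries, and the ribosomal protein list reaches 1.02 in OPE 3.

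The other 20 lists did not pass as groups, among them the cartilage matrix, hedgehog and erythroid lists above. Camera adjusted p was 0.0567 for skeletal muscle, 0.0643 for matrix remodelling, 0.134 for replication-dependent histones, 0.185 for neural crest derivatives and for mitochondrially encoded genes, and 0.209 for BMP signalling. It was 0.253 for primary cilium, 0.413 for retinoic acid, 0.421 for joint interzone and for sex-linked genes, 0.477 for immediate early genes and 0.536 for dermal fibroblasts. It was 0.605 for interferon and inflammation and for heat shock, 0.833 for thyroid and glucocorticoid response, 0.844 for NRF2 and oxidative stress and 0.878 for xenobiotic metabolism. Bmp7, of the BMP list, passed over all genes, as did Col22a1, a collagen of tissue junctions in the joint interzone list (-0.81 ± 0.12, adjusted p = 0.0209). The thyroid and glucocorticoid list had a median below 0 and a mean above 0, and the median and fry differed in sign for the xenobiotic list. In the xenobiotic list Cyp1b1, a target of the aryl hydrocarbon receptor, gave 0.71 ± 0.13 (adjusted p = 0.0516).

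Cytosolic ribosomal protein genes were higher, most in OPE 3. No gene of 84 passed, over all genes or over the list alone, 83 had a log2 fold change above 0, and the list rose as a group (camera adjusted p = 1.22e-19; adjusted p = 0.45 with an estimated correlation). Its median was 1.02 in OPE 3 and between 0.04 and 0.27 in the other OPE libraries, and without OPE 3 the list still passed (adjusted p = 3.25e-14) with a median of 0.17. Ribosomal protein genes took 8.85% of the counts in OPE 3 and between 4.43% and 5.69% in the 7 other libraries (OPE against vehicle, exact permutation p = 0.0571, two-sided, adjusted p = 0.571 over 10 library properties). In OPE 3 short genes were also high and long genes low: the tenth of genes with the shortest transcripts had a median of 0.58 and the tenth with the longest -0.39, and no other library exceeded 0.17 in either. The smallest p of this test with 4 against 4 libraries is 0.0286, so a single property could not pass the adjustment over 10, and that none passed does not show that the groups were alike in them.

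**Figure D3:**
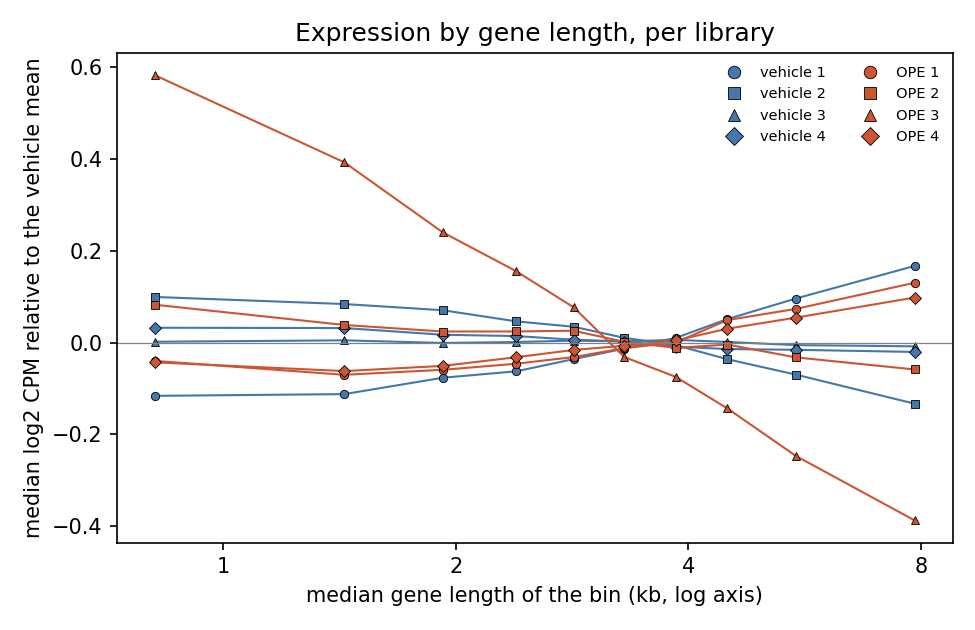
Median log2 CPM relative to the vehicle mean (vertical axis) for 10 bins of tested genes ordered by gene length (horizontal axis, kilobases, log scale), 1 line per library, vehicle in blue and OPE in red. OPE 3 goes from 0.58 in the bin of shortest genes to -0.39 in the bin of longest genes, while the other libraries stay between -0.13 and 0.17.

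The authors' deposited table gives 476 genes at an adjusted p under 0.05, 156 higher and 320 lower with OPE. All 74 genes of the edgeR test were among them with the same sign; both lists rest on the same counts, so this is no independent evidence. In the authors' deposited table the log2 fold changes run from -1.73 for Csf1r to 1.47 for Gdf15.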

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

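The tests of other explanations in this part were chosen after the values they bear on had been seen, except the yolk sac test, whose genes had not been looked at; the search for libraries far from the rest of their group was planned. After a first result, 3 of these tests were also altered: the prior count of the test for an equal macrophage loss went from 2 to 0.5, which left its p as it was, the bound of the intestinal test was loosened, as told there, and the test of OPE 3 alone came to count the length-corrected medians, which turned its outcome. A library was singled out when its gap to the nearest of its group, as a share of the group's range, exceeded Dixon's 95% limit for 4 values. This was asked of 408 groups of 4 values; 25 passed, where chance gives about 20.

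OPE 1 was set apart by 7 results. It had more reads, 21806141 against at most 15520091 in the other OPE libraries (gap 0.922 of the range). It had higher Sesn2 (0.984), Slc7a11 (0.843), Tmcc2 (0.834) and Hist2h2bb (0.921), and lower Rrm2 (0.947) and Mcm5 (0.891). OPE 3 stood apart with a low TMM factor of 0.93 (gap 0.870), a high NRF2 and oxidative stress list (0.919), a low primary cilium list (0.856), and high Hoxd9 (0.854), Id2 (0.877), Crabp1 (0.899) and Hspe1 (0.927). OPE 2 was high in Pfkfb3 (0.875), and OPE 4 was low in Pmaip1 (0.844). In the vehicle group, vehicle 1 was high in Stab1 (0.954) and Cx3cr1 (0.844) and low in Ifitm5 (0.915), Mthfd2 (0.89) and Hmox1 (0.941), vehicle 3 was high in Cyp1b1 (0.899) and low in Ofd1 (0.948), and vehicle 4 was high in Col13a1 (0.846) and Hist1h2be (0.847).

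The fall of macrophage genes with OPE was set against technical causes. Removing the trends of gene length and GC content from each library left the list's median at -1.20 against -1.19 before, all 4 OPE libraries below the vehicle libraries and 12 members past the threshold, which argues against such a trend as the cause. Less blood in the OPE libraries is argued against by the erythroid list, whose median log2 fold change was 0.14 (-0.11 without OPE 3) and which lay at least 0.83 above the macrophage list in each OPE library. A smaller share of macrophages would lower alike only those transcripts that no other cell of the bud makes. The members' deviations from the list's median differed between the groups (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 libraries can give), with quartiles of the log2 fold changes at -1.74 and -0.90. An equal loss is thus not the whole account; fewer macrophages together with expression of some members in other cells, and a change of expression within macrophages under the treatment, stay open and were not told apart by a test.

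The higher ribosomal protein genes were weighed against a length trend and against OPE 3 alone. Removing each library's gene-length trend left the list's median at 0.34 against 0.44 before (camera adjusted p = 1.02e-17), which argues against the trend as the whole cause. Without OPE 3 the uncorrected median was 0.17, and OPE 4, at 0.04, lay inside the vehicle range of -0.09 to 0.12. The list still passed without OPE 3 (camera adjusted p = 3.25e-14). Both p-values are from camera at the preset correlation of 0.01. At its estimated correlation of 0.866 the uncorrected list did not pass with all libraries (camera adjusted p = 0.45). With the length trend removed, OPE 1 to 4 stood at 0.25, 0.20, 0.66 and 0.08, all above the highest vehicle median of 0.06, OPE 4 by little, so the rise was largest in OPE 3 but not in that library alone. What set OPE 3 apart, and whether the treatment raised these genes, stays open and was not tested.

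Genes typical of gut epithelium were lower with OPE: Fabp2 had 2 reads over the 4 OPE libraries and 131 over the vehicle libraries (ratio 0.0187, exact 95% interval 0.00224 to 0.069), Apob had 2 and 78, and Apoa1 and Lct passed too. Fabp2, Apob and Lct lie outside the rule for named genes and were chosen after their values were seen. For yolk sac tissue in the vehicle libraries, 13 other yolk sac endoderm genes had a median log2 ratio of -0.0254 (quartiles -0.26 and 0.15). The bound written beforehand counted this median against yolk sac tissue. The median cannot decide all the same, because most of the 13 were higher than Apob (0.95 CPM) with vehicle. Examples are Dab2 (175 CPM) and Ctsc (20.7 CPM), and such levels would hide a small share of yolk sac. Among the 13 genes, those below Apob with vehicle went both ways at low counts. Amn (0.391 to 0.613 CPM, vehicle to OPE), Apom (0.296 to 0.471) and Slc13a4 (0.495 to 0.56) were not lower. Apoc2 and Ambp were lower, with 10 and 13 vehicle reads and 2 and 6 OPE reads. Ttr, abundant in yolk sac, had 6 vehicle reads, which argues against such tissue on this gene alone. The intestinal test left out Fabp2, Apob, Apoa1, Lct, Cdh17 and Vil1, all seen to be lower, and the 7 other genes tested from that list had a median log2 fold change of -0.00903, which the bound first written counted against intestinal tissue. That bound was loosened after this value was seen. The reason was that 6 of the 7 were higher than Fabp2 in the vehicle libraries, which would hide a small share. Of the members too low to be tested, Muc13 and Krt20 were lower with OPE (49 and 49 vehicle reads, 10 and 22 OPE reads). The others, Cdx1 and Guca2a, had at most 5 reads in either group. Intestinal tissue and a change within the limb bud thus cannot be told apart here.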

How the results depend on the processing

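None of the 74 called genes changed sign in any of the fits, and none of the 16 lists that passed changed direction. Among what had not passed, 6 of the 158 named genes crossed 0, Acan, Col2a1 and Sox9 among them, and so did several lists, for example erythroid, NRF2 and oxidative stress, and interferon and inflammation without vehicle 1. The number of genes past an adjusted p of 0.05 was 74 and moved by over 1.5 times with library totals only (131), with a filter of at least 1 count in any library (136), with DESeq2 (504), with voom and sample quality weights (445), at an adjusted p of 0.01 (7) or at 2-fold or more (45), and, among settings chosen after seeing the data, with the newer quasi-likelihood method (112), length-corrected offsets (321) and length- and GC-corrected offsets (357); 74, 71 and 72 of the main calls were among those of DESeq2, the length and GC correction and the length correction. Leaving out 1 library gave between 7 (without vehicle 2 or vehicle 4) and 308 (without OPE 3) genes. There were 8 without vehicle 1, 12 without OPE 2, 19 without vehicle 3, 58 without OPE 1 and 178 without OPE 4. The share of calls that were higher was 8.11% and rose to 18.4% with the lowest count filter, 33.3% with DESeq2, 29.4% with voom and sample weights, 17.0% with the newer method, 27.1% without OPE 1 and OPE 3, 47.0% with the length correction and 50.7% with the length and GC correction, and it lay between 5.26% and 27.0% when 1 library was left out. Of 36 lists 16 passed, 0 with an estimated correlation and 6 with fry, and between 13 and 19 without 1 library. Of the 158 named genes 36 passed, 84 with DESeq2, 61 with the length correction, 63 with the length and GC correction, and between 7 and 55 without 1 library. The cause of these moves was not tested.

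The labels do not say whether a replicate number marks a shared litter or culture day, and the main fit did not use the numbers as pairs. The deviations of same-numbered libraries from their group means correlated with r between 0.0127 and 0.31, over 0.1 in 1 of 4 pairs. Of the 8 libraries, 4 correlated best with their own number. These values do not settle whether the numbers pair the samples. With the number as a block, 62 genes passed (44 of them among the 74; 9.68% higher), and 18 lists and 25 named genes. The cartilage matrix, matrix remodelling and skeletal muscle lists then passed as lower (camera adjusted p = 0.0475, 0.0481 and 0.0166), and the limb patterning list and its member Fgf4 did not pass (0.0557 for the list). At these depths the simulated data gave 29.9% of 1.5-fold changes called, so changes of this size are mostly missed. The pseudocount alternatives were not run, since the values are counts.

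As many genes as with the real grouping came from 1 of the 35 splits of the 8 libraries into 4 and 4, the real one. The highest count of the others was 0 genes. Every other split mixes OPE and vehicle libraries, which puts a group difference into the spread and lowers its count. With only 35 splits, the real one can be no rarer than 1 in 35. Chance is therefore not excluded by this for the count of genes. For the lists, 6 of the 35 splits gave at least 16 past the threshold, with 20 as the highest of the others, so chance cannot be excluded for the count of lists at the preset correlation.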

Other observations

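The lists and tests in this part were chosen after the data had been seen. Lysosomal genes were mostly higher with OPE: 45 of 56 had a log2 fold change above 0, none passed over all genes, 16 rose and 1 fell adjusted over the list alone, and the list rose as a group (camera adjusted p = 4.62e-09; adjusted p = 0.22 with an estimated correlation). Lamp2, a lysosomal membrane protein, and Flcn, a regulator of nutrient sensing at the lysosome, gave 0.57 ± 0.11 and 0.72 ± 0.14 (edgeR adjusted p = 0.0522 for each). Of 20 aminoacyl-tRNA synthetase genes, none passed over all genes and 10 rose adjusted over the list alone, with Yars at 0.59 ± 0.13 (adjusted p = 0.0734); the list rose (camera adjusted p = 2.75e-07; adjusted p = 0.24 with an estimated correlation). Its medians in the OPE libraries lay between 0.18 and 0.64, above all vehicle libraries.

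Among 16 targets of the sterol receptor LXR, 3 fell over all genes (Lpl, Abcg1 and Apoc1, the last at -2.22 ± 0.41, adjusted p = 0.0452) and 6 adjusted over the list alone, and the list fell (camera adjusted p = 9.91e-05; adjusted p = 0.15 with an estimated correlation). Abca1 and Apoe gave -0.68 ± 0.13 and -0.68 ± 0.14 (adjusted p = 0.0544 and 0.0656). The fall was not shared by all members, and 4 of the 16 had a log2 fold change above 0. Srebf1 and Fasn gave -0.14 ± 0.09 and -0.06 ± 0.12 (adjusted p = 0.528 and 0.89). Scd1 and Scd2 gave 0.38 ± 0.18 and 0.22 ± 0.10 (adjusted p = 0.402 and 0.388). The LXR and apical ectodermal ridge lists were written after Lpl, Abcg1, Bmp7 and Fgf4 had been seen to be lower, so their tests are not independent of these genes. Macrophages express Lpl, Abcg1, Apoc1 and Apoe, and the macrophage list was lower in the same libraries (median -1.19, all 21 members below 0). In the apical ectodermal ridge list 2 of 18 genes fell, Bmp7 and Fgf4, and the list fell (camera adjusted p = 0.00549; adjusted p = 0.26 with an estimated correlation); Fgf17 gave 0.83 ± 0.26 (adjusted p = 0.201). Osteoclast genes did not move as a group (camera adjusted p = 0.614), and 2 rose and 2 fell adjusted over the list alone. Mmp9 gave 1.00 ± 0.26 (adjusted p = 0.115), with 95.7 CPM in OPE 1 and 37.8 to 52.1 CPM in the other OPE libraries. Tnfrsf11a and Acp5 gave -0.85 ± 0.25 and -0.45 ± 0.15 (adjusted p = 0.17 and 0.233). Of 13 intestinal genes 4 fell, which are the genes for which the list was written, so its set test shows nothing further. Of 11 yolk sac genes tested 2 fell, Apob and Apoa1, which had been seen before that list was written; the other 9 lay between -0.34 and 0.61 and none passed. Ibsp, bone sialoprotein, which lies outside the rule for named genes and was chosen after its value was seen, gave the lowest value of the osteoblast list at -3.33 ± 0.64 (adjusted p = 0.0522), and the macrophage elastase gene Mmp12 gave 2.77 ± 0.52 (adjusted p = 0.0501).

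A hypothesis from these values is that the OPE cultures reached the late stages of endochondral ossification less far than the vehicle cultures. To compare the 2 lists, each gene was taken relative to its mean over all 8 libraries, not over the vehicle libraries as elsewhere. Only the gap between the groups, -0.46, therefore has a meaning, not the sign within a group. Per library, the hypertrophic list's median minus that of the cartilage matrix list averaged -0.23 ± 0.09 (SD, n = 4) with OPE and 0.23 ± 0.10 with vehicle (exact permutation p = 0.0286, two-sided, the smallest possible). This restates the list medians that prompted the hypothesis and, given those, could hardly have come out otherwise, so it leaves the hypothesis undecided. Mmp13, a gene of terminal hypertrophic cartilage, was too low to be tested. It had 111 reads in OPE 1, 19, 21 and 8 in OPE 2, 3 and 4, and 5 to 10 in the vehicle libraries. These reads are not scaled to depth, and OPE 4 had fewer reads in total (14986793) than any vehicle library (at least 17549560). Scaled to depth, the pooled ratio of OPE over vehicle was 6.73 (exact 95% interval 4.51 to 10.4, counting error only). That direction is opposite to what the hypothesis foresees, though most of the reads came from OPE 1.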
